A study of Arabidopsis thaliana with 12 samples.

How the data were processed

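RNA from green tissue of 3-week-old Arabidopsis thaliana seedlings was measured on 12 one-colour Affymetrix ATH1 arrays, 3 biological replicates in each of 4 groups. The groups were an RNA interference (RNAi) line against CHLD given 20 µg/ml dexamethasone, Col-0 wild type given the same dexamethasone, a CHLM overexpression line given 20 µM β-estradiol, and Col-0 given the same β-estradiol. Dexamethasone and β-estradiol are the steroids that switch on inducible transgenes of this kind, and each Col-0 group received the inducer of the line it is set against. Groups and replicate numbers were taken from the sample labels.

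The deposited values were log2 signal values, 1 column per array, and the authors made them with Affymetrix Expression Console, per the submitters' processing notes. The software version, the summary method and the normalization were not given in the sources used here. The log base was not stated either, and was taken as 2 because the values of all 12 arrays lay between 2.39 and 14.49. Array medians lay between 6.26 and 6.32, so the arrays were already on a common scale, and the values were used as deposited with no further normalization. All 12 columns of values were used and 0 were left out.

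The table held 22809 probe sets. The 63 AFFX control probe sets were left out, and 22746 were tested. Locus codes were attached through the annotation used here, which gave a single gene to 13513 probe sets, several genes to 503 and no gene to 8730. Of the probe sets with 1 gene, 13436 were found in the RefSeq gene table of assembly TAIR10.1, and 1535 of these genes had a symbol other than the locus code. Genes are named below by that symbol, or by the locus code where there is none. Probe sets without a gene count in all totals and are not named. CHLD was among the genes with no probe set named here, so the knockdown of the target itself is not analysed here. For 146 genes with more than 1 probe set, the one with the highest mean over the 12 arrays stands for the gene.

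Differences between groups were computed in R 4.3.3 with limma 3.58.1. All 12 arrays entered 1 linear model of 4 groups, with moderated tests (eBayes without a variance trend and without robust fitting, 8 residual and 6.05 prior degrees of freedom). P-values were two-sided and adjusted by Benjamini-Hochberg over the 22746 probe sets of each comparison, and an adjusted p under 0.05 counted as a change, with no minimum fold. A second count asked for a change of at least 2-fold as well. The comparisons were each line against Col-0 with the same inducer, Col-0 under dexamethasone against Col-0 under estradiol, and the difference between the effects in the lines (the CHLM effect minus the CHLD effect). Errors of log2 differences are standard errors (SE) from limma, and errors of group means are standard deviations (SD) over 3 arrays. The correlation of the effects runs across probe sets, which are not independent replicates, and carries no p-value.

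Gene lists were tested with camera from limma at an inter-gene correlation of 0.01, on 1 probe set per gene over 13356 genes, adjusted by Benjamini-Hochberg over the 50 lists with at least 3 measured members. The camera test at a correlation estimated for each list, and fry, were run beside it. The comparisons, tests, thresholds, 28 gene lists and the rule for naming genes were fixed before the data were examined. Apart from the plastid and mitochondrial lists, these lists named 375 genes. Only 51 of these 375 had a probe set of their own with a gene name. The plastid list took every plastid locus, and the mitochondrial list took loci whose symbols start with nad, cox, ccb, matR or orfX. Another 8 members were left out because the reference does not give the locus the name that was written, and 9 of the 28 lists had 3 or more measured members. For this reason 41 further lists were put together from the symbols in the reference, after the gene names were seen to be incomplete and before any difference in expression was computed.

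The rule named CHLD and CHLM. It then named, for each comparison, the 10 largest rises and 10 largest falls among probe sets with 1 gene whose groups did not overlap. From each list described it named up to 4 members past the threshold, the 2 largest rises and the 2 largest falls, or the member with the smallest p where none passed. Across the lines it named 5 genes changed in the same direction and 5 in opposite directions, by the larger size of the smaller change. For the difference between the effects, overlap of groups cannot be defined, and the 10 largest of each sign past the threshold were taken, a choice made after the data were seen.

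The tests were checked on simulated data of the same size, with 200 of 22746 probe sets changed. At a log2 difference of 1, 95.5% of changed probe sets were recovered for the CHLD comparison, 86.6% for the CHLM comparison, 94% for the Col-0 comparison and 73.1% for the difference between the effects. At a log2 difference of 0.5 these shares were 58.2%, 35.8%, 56.7% and 16.4%. Each share rested on 67 changed probe sets, and all groups were simulated with the same spread per probe set. The CHLD, CHLM and Col-0 shares therefore differ by the random draw and not by a property of the comparison. No array that stands apart was simulated. For arrays, their number limits the precision: 3 per group.

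The alternatives tried were the replicate number as a block, quantile normalization, median centring, a variance trend with robust fitting, array weights, only the groups compared, no dim probe sets (mean below the 30th percentile), no probe sets of the cross-hybridising types, the mean of all probe sets of a gene in the list tests, an adjusted p of 0.01, leaving out each array in turn, and, chosen after the data were seen, only the lists written first.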

Results

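Gene expression was measured in green tissue of 3-week-old Arabidopsis seedlings in which a step of chlorophyll synthesis had been altered by an inducible transgene. CHLD encodes a subunit of magnesium chelatase, which inserts magnesium into protoporphyrin IX, and CHLM encodes the methyltransferase that acts on the product of that enzyme. The CHLD RNAi line and Col-0 wild type were both given dexamethasone, and the CHLM overexpression line and Col-0 were both given β-estradiol, with 3 biological replicates in each of the 4 groups. The 12 arrays gave log2 signal values with medians between 6.26 and 6.32, and pairs of arrays were correlated at 0.983 to 0.997 across probe sets. Replicate 1 of Col-0 under estradiol stood apart from its group. It was correlated at 0.99 with replicates 2 and 3, which were correlated at 0.997 with each other, and at a mean of 0.993 with the Col-0 dexamethasone arrays. The lowest correlation within any of the other groups was 0.994.

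The targeted gene CHLM was measured first. In the CHLM overexpression line its log2 signal was 14.48, 13.96 and 14.24 in the 3 replicates, against 11.71, 11.72 and 11.68 in Col-0 under estradiol. This was a 5.75-fold rise (log2 difference 2.52, SE 0.127, n = 3 per group, limma adjusted p = 1.30e-07). The 14.48 of replicate 1 lay next to the top value of the whole data set, 14.49, so the upper end of the array's range bounds what the fold could show. In the CHLD RNAi line CHLM was at 11.65 ± 0.18 (SD, n = 3) against 11.70 ± 0.13 in Col-0 under dexamethasone, which was not past the threshold (log2 difference -0.04, adjusted p = 0.886). CHLD itself was not analysed here, so the size of its knockdown is left open.

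**Figure D1:**
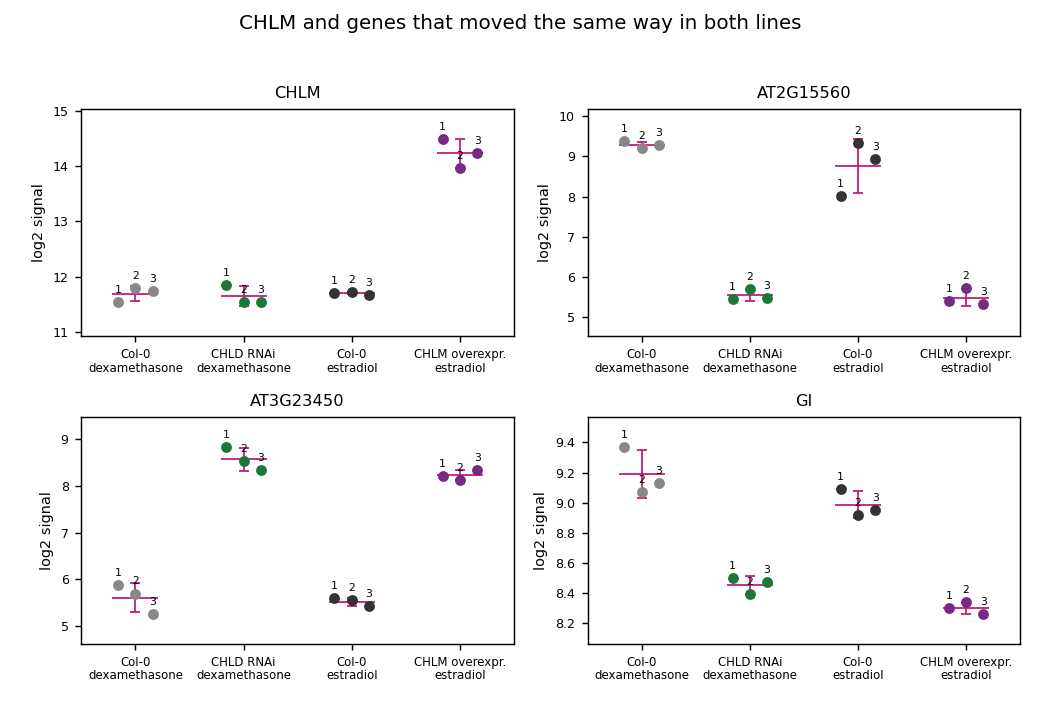
Log2 signal of CHLM, AT2G15560, AT3G23450 and GI in each of the 12 arrays, by group, with points numbered by replicate and the bar showing the mean ± SD of 3 arrays. CHLM is raised in the CHLM overexpression line, at 14.23 ± 0.26 against 11.70 ± 0.02 in Col-0 with the same inducer, while AT2G15560 and GI are lower and AT3G23450 is higher in both lines than in their Col-0 groups.

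The comparison of the CHLD RNAi line with Col-0 under dexamethasone asks which transcripts follow a knockdown of magnesium chelatase. SWEET13, a sucrose transporter, rose 7.71-fold, from 6.12 ± 0.36 to 9.07 ± 0.16 (SD, n = 3; log2 difference 2.95, SE 0.162). JMT, the methyltransferase that makes methyl jasmonate, rose 4.73-fold (log2 difference 2.24, SE 0.165), and DFR and UF3GT, enzymes of anthocyanin synthesis, rose 2.98-fold and 2.36-fold. IAA29, an auxin response gene, fell 4.41-fold (log2 difference -2.14, SE 0.154), and AT4G33150, the bifunctional enzyme of lysine breakdown, fell 3.29-fold (-1.72, SE 0.362). The evening clock gene GI fell 1.67-fold (-0.74, SE 0.0933, adjusted p = 1.94e-04).

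The largest rises were those of AT1G26290 (log2 difference 3.70, SE 0.146, adjusted p = 2.31e-09) and AT3G61490 (3.64, SE 0.173, adjusted p = 1.07e-08). AT1G80280, AT3G19430, AT3G23450, SWEET13, AT3G14395, ATMPK13, AT4G14815 and AT3G17050 followed, at log2 differences from 3.39 down to 2.78. The largest falls were those of AT2G15560 (-3.74, SE 0.234, adjusted p = 1.51e-07), AT4G29200 (-3.50) and AT2G12050 (-3.16), with AT3G47320, AT5G39520, AT3G28320, the peroxidase gene AT2G37130, AT3G15450, IAA29 and AT4G33150 between -2.72 and -1.72. These genes were picked among those whose groups did not overlap. By that rule all 3 arrays of the line lay on one side of all 3 Col-0 arrays. In total 2822 of 22746 probe sets (12.4%) passed the threshold, 1381 higher and 1441 lower in the line, and 284 of them changed at least 2-fold (176 higher, 108 lower). Groups without overlap were seen in 31.7% of all probe sets, where chance gives 10%. The total fell to 1666 without Col-0 dexamethasone replicate 1, 1563 without replicate 2 and 1801 without CHLD RNAi replicate 2. The call of AT5G39520 (adjusted p = 0.035) ended without any 1 of the 6 arrays compared, with adjusted p between 0.0526 and 0.119. Col-0 estradiol replicate 1, outside this comparison but part of the shared estimate of spread, was at 9.69 for this gene. Replicates 2 and 3 were at 6.05 and 5.85. Without replicate 1 the fall of AT5G39520 was -2.44 (SE 0.211, limma adjusted p = 2.08e-06).

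Among the gene groups, the listed transcripts of the mitochondrial genome rose as a group (camera adjusted p = 0.0234). Of 16 measured, 3 rose and 0 fell, or 4 and 0 adjusted over the list alone, with a median log2 difference of 0.23. This call was lost with an estimated correlation (adjusted p = 0.526 with an estimated correlation) and without CHLD RNAi replicate 2 (adjusted p = 0.126). The cytochrome c maturation gene ccb452 rose by 0.90 (SE 0.144), and nad1 of respiratory complex I by 0.66 (SE 0.194), as did 3 of its 6 other probe sets, by 0.39 to 0.42 (adjusted p between 0.00607 and 0.0367). The other 3, which were dimmer, stood at 0.20, -0.06 and -0.003. The nad1 call (adjusted p = 0.0403) ended without Col-0 dexamethasone replicate 2 or 3, without CHLD RNAi replicate 1, 2 or 3, without Col-0 estradiol replicate 2 or without CHLM replicate 2, with adjusted p up to 0.16. Tubulin genes fell (camera adjusted p = 0.00216; adjusted p = 0.147 with an estimated correlation). Of 7 measured, 3 fell, with TUB1 at -0.96 (SE 0.124) and TUB9 at -0.47 (SE 0.0982). Autophagy genes of the ATG8 system, which build the autophagosome, fell too (camera adjusted p = 0.0197; adjusted p = 0.664 with an estimated correlation). Of 10 measured, 2 fell, ATG8F by 0.65 (SE 0.152) and APG8H by 0.47 (SE 0.104). The group was not past the threshold without CHLD RNAi replicate 1 (adjusted p = 0.0509), nor was ATG8F without Col-0 dexamethasone replicate 2 (adjusted p = 0.067).

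Plastid-encoded transcripts moved both ways. Of 69 measured, 10 rose and 5 fell, or 12 and 6 adjusted over the list alone, and the group as a whole was not past the threshold (camera adjusted p = 0.173). The largest rises were those of psbD, which encodes the D2 protein of photosystem II (log2 difference 1.92, SE 0.165, adjusted p = 3.98e-06), and ndhG (1.37, SE 0.227). The largest falls were those of psbA, which encodes the D1 protein (-0.75, SE 0.108, adjusted p = 5.63e-04), and psbN (-0.70, SE 0.159). Of 9 measured genes of chlorophyll synthesis 1 rose and 1 fell, the same number as when adjusted over the list alone. CHLI2, a minor magnesium chelatase subunit, rose by 0.33 (SE 0.0967, adjusted p = 0.0387) and PORB, a protochlorophyllide reductase, fell by 0.30 (SE 0.0891, adjusted p = 0.0431). The CHLI2 call ended without Col-0 dexamethasone replicate 1, 2 or 3, CHLD RNAi replicate 1 or 2, or Col-0 estradiol replicate 3 (adjusted p between 0.0503 and 0.152). The PORB call ended without any 1 of the 6 arrays compared or Col-0 estradiol replicate 3 (adjusted p between 0.0522 and 0.143). The median of the chlorophyll list was -0.04 and its mean 0.01, camera gave a downward sign with adjusted p = 0.944, and without CHLM the median was 0.04 with adjusted p = 0.984. No member passed among 3 light-harvesting genes (smallest p LHCB4.2, -0.09), 6 of photosystem subunits and electron transport (PSBW, -0.13) and 3 of the Calvin cycle (SBPASE, 0.22). Of 4 senescence genes WRKY53, a senescence-linked transcription factor, rose by 1.09 (SE 0.16, adjusted p = 6.33e-04). Of 3 markers of other cell types of green tissue 0 rose and 1 fell, FMA. The FMA call ended without Col-0 dexamethasone replicate 2 or 3 or CHLD RNAi replicate 2 or 3 (adjusted p between 0.0896 and 0.141). Both measured flavonoid genes, DFR and UF3GT, rose, and both measured clock genes, GI and COR27, fell, over all probe sets and adjusted over the list alone. The COR27 call (-1.17, SE 0.336, adjusted p = 0.0353) ended without Col-0 dexamethasone replicate 1 or 2 or any CHLD RNAi replicate (adjusted p between 0.058 and 0.122). Without Col-0 estradiol replicate 1, which enters the shared spread, the SE of COR27 was 0.143 (limma adjusted p = 7.35e-05). LTI30, not past the threshold with all arrays, then passed with a fall (-1.75, SE 0.297, limma adjusted p = 0.00114).

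The comparison of the CHLM overexpression line with Col-0 under estradiol asks which transcripts follow an excess of the methyltransferase. QQS, a gene known to affect starch content, fell 15.7-fold, from 9.10 ± 0.06 to 5.13 ± 0.17 (SD, n = 3; log2 difference -3.97, SE 0.153, adjusted p = 6.74e-09). THI2.1, a thionin of jasmonate-dependent defence, fell 26.1-fold, from 8.84 ± 2.04 to 4.14 ± 0.09 (-4.70, SE 0.83, adjusted p = 0.00487). HIS1-3, a linker histone linked to drought, fell 5.02-fold (-2.33, SE 0.277), and JRG21, a jasmonate-regulated oxygenase, fell 5.83-fold (-2.54, SE 0.296). Apart from CHLM itself, the plastid transcript psbD rose 4.09-fold (2.03, SE 0.165), and WSD1, a wax ester synthase, rose 2.55-fold (1.35, SE 0.223).

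The largest rise was that of AT3G23450 (log2 difference 2.71, SE 0.149, adjusted p = 2.85e-07), followed by CHLM and AT3G17050 (2.51, SE 0.151). After psbD came AT2G27420, AT5G46730, AT1G65490, WSD1 and AT3G44970, from 1.85 downward, and the plastid gene ndhG (2.46-fold). The falls of AT2G15560 (-3.27, SE 0.234), AT1G54020 (-3.08, SE 0.663), AT4G29200 (-2.90), AT2G12050 (-2.71), AT3G47320 (-2.62) and AT4G33150 (-1.96) completed the 10 largest among genes whose groups did not overlap. By that rule all 3 arrays of the line lay on one side of all 3 Col-0 arrays in each gene. PDF1.2b, described below, was left out by it, though its fall was larger than several of these. In total 2217 probe sets (9.75%) passed the threshold, 1238 higher and 979 lower. Among the 153 that changed at least 2-fold, 33 were higher and 120 lower. Groups without overlap were seen in 26.3% of all probe sets, against 10% by chance. The total was 1156 without CHLM replicate 1. Without Col-0 estradiol replicate 1, the array that stood apart, it was 1501, 746 higher and 755 lower, so that the excess of rises was absent, and of these 1256 were among the 2217 with the same direction.

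Genes of the jasmonate response fell as a group (camera adjusted p = 1.43e-04; adjusted p = 0.326 with an estimated correlation). Of 12 measured, 5 fell and 1 rose, with THI2.1 and the defensin gene PDF1.2b (-2.92, SE 0.79, adjusted p = 0.0335) as the largest falls and the transcription factor gene MYC4 as the rise (0.47, SE 0.108). Col-0 estradiol replicate 1 was itself at 6.48 for THI2.1 and 5.19 for PDF1.2b, where replicates 2 and 3 were at 10.05 and 9.99, and at 9.20 and 9.42. Without it the falls were -5.88 and -4.29. Col-0 under dexamethasone was at a mean of 6.99 for THI2.1 and 5.14 for PDF1.2b. The fall of PDF1.2b therefore rested on the high level of Col-0 estradiol replicates 2 and 3. The PDF1.2b call ended without Col-0 estradiol replicate 2 or 3 or CHLM replicate 1 or 2 (adjusted p between 0.0834 and 0.114), and the MYC4 call without CHLM replicate 3 (adjusted p = 0.0561). Cold and dehydration genes fell (camera adjusted p = 0.00274; adjusted p = 0.653 with an estimated correlation), with 2 of 14 past the threshold, HIS1-3 and XERICO (-0.71, SE 0.168). That group's call ended without Col-0 estradiol replicate 1 (adjusted p = 0.231), in which 13 of its 14 members lay higher than in replicates 2 and 3, and the XERICO call without CHLM replicate 1 (adjusted p = 0.0751). The fall of XERICO was smaller without Col-0 estradiol replicate 1, at -0.46 (SE 0.118, adjusted p = 0.0318).

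The ATG8 autophagy genes fell (camera adjusted p = 1.16e-04; adjusted p = 0.451 with an estimated correlation). Of 10 measured, 5 fell, the most APG8A (-0.69, SE 0.146) and ATG8E (-0.56, SE 0.134), the latter not past the threshold without Col-0 estradiol replicate 1 (adjusted p = 0.061) or CHLM replicate 1 (adjusted p = 0.0764). Genes for RNA editing in organelles rose (camera adjusted p = 0.0033; adjusted p = 0.451 with an estimated correlation). Of 15 measured, 4 rose, led by OTP81 (0.72, SE 0.194) and MEF8S (0.55, SE 0.0889), and the OTP81 call ended without Col-0 estradiol replicate 1 or 3 or CHLM replicate 1 or 2 (adjusted p between 0.0504 and 0.126). The listed mitochondrial transcripts rose (camera adjusted p = 0.00911, and 0.451 with an estimated correlation). Of these, 4 of 16 were past the threshold, or 6 adjusted over the list alone, among them ccb452 (0.86, SE 0.144) and nad4L (0.76, SE 0.142). Without Col-0 estradiol replicate 2 the group stood at adjusted p = 0.0622. The iron-regulated bHLH transcription factors fell (camera adjusted p = 0.0299; adjusted p = 0.326 with an estimated correlation), with 2 of 7 past the threshold, BHLH101 (-0.86, SE 0.201) and ILR3 (-0.36, SE 0.0836). These calls ended without Col-0 estradiol replicate 2 for the group (adjusted p = 0.0667), CHLM replicate 2 for BHLH101 (0.0584) and Col-0 estradiol replicate 1 for ILR3 (0.0553). Genes of the endoplasmic reticulum stress response fell (camera adjusted p = 0.0442; adjusted p = 0.326 with an estimated correlation). Of 14 measured, 1 fell, DER2.1 (-0.62, SE 0.0929), and 1 rose, ATERDJ2B (0.33, SE 0.0916). The group's call ended without Col-0 estradiol replicate 2 or 3 or CHLM replicate 2 (adjusted p = 0.151, 0.0605 and 0.0549), and that of ATERDJ2B without CHLM replicate 1, 2 or 3 or Col-0 estradiol replicate 1 or 3 (adjusted p between 0.0708 and 0.113).

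Of the 69 plastid-encoded transcripts 13 rose and 3 fell, or 14 and 4 adjusted over the list alone (camera adjusted p = 0.205; adjusted p = 0.866 with an estimated correlation). Without Col-0 estradiol replicate 1 the group passed upward (camera adjusted p = 0.00589). Apart from psbD, ndhG rose 2.46-fold (SE 0.227 on the log2 scale), while psbA fell by 0.57 (SE 0.108) and the ribosomal protein gene rps19 by 0.51 (SE 0.105). Of the 9 genes of chlorophyll synthesis 2 rose, CHLM and CHLI2 (0.45, SE 0.0967), and PORB fell by 0.40 (SE 0.0891), with 4 rising and 1 falling adjusted over the list alone. The PORB call ended without Col-0 estradiol replicate 2 (adjusted p = 0.0513) or CHLM replicate 1 (adjusted p = 0.0573). Camera gave adjusted p = 0.25 for this list, and without CHLM its median was 0.12 with adjusted p = 0.81. No member passed among the light-harvesting (smallest p LHCB4.3, 0.29), photosystem (PSAN, 0.08) and Calvin cycle genes (PRK, -0.15). WRKY53 rose by 0.60 (SE 0.16, adjusted p = 0.0314), a call that ended without Col-0 estradiol replicate 1, CHLM replicate 2 or CHLM replicate 3 (adjusted p = 0.0797, 0.0638 and 0.1). Its value was smaller without Col-0 estradiol replicate 1, at 0.38 (SE 0.122). GI fell by 0.69 (SE 0.0933, adjusted p = 9.98e-04), and both clock genes fell adjusted over the list alone, with COR27 at -0.86 (SE 0.336, adjusted p = 0.124 over all probe sets). The COR27 value rested on single arrays, at -1.19 (adjusted p = 0.0473) without Col-0 estradiol replicate 3 and -0.29 (SE 0.16, adjusted p = 0.323) without replicate 1, which was at 6.05 against 4.43 and 4.25 in replicates 2 and 3.

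Much of the change was common to the lines. AT2G15560 fell 13.4-fold in the CHLD RNAi line and 9.65-fold in the CHLM overexpression line, and AT4G29200, AT2G12050 and AT3G47320 fell between 6.16-fold and 11.3-fold in both. AT3G23450 rose 7.84-fold in the CHLD RNAi line and 6.56-fold in the CHLM overexpression line. These were the 5 genes with the largest changes in one direction across the lines. The log2 differences of the lines were correlated at Pearson r = 0.539 and Spearman rho = 0.547 across 22746 probe sets, and the lines share no control arrays. In both lines 535 probe sets were higher, where independent lists would share 75.2, and 513 were lower, where independent lists would share 62. Another 22 probe sets passed the threshold in opposite directions. At a change of at least 2-fold, 18 probe sets were higher and 45 lower in both. Without Col-0 estradiol replicate 1, r was 0.439, with 412 higher in both, 375 lower in both and 53 in opposite directions.

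**Figure D2:**
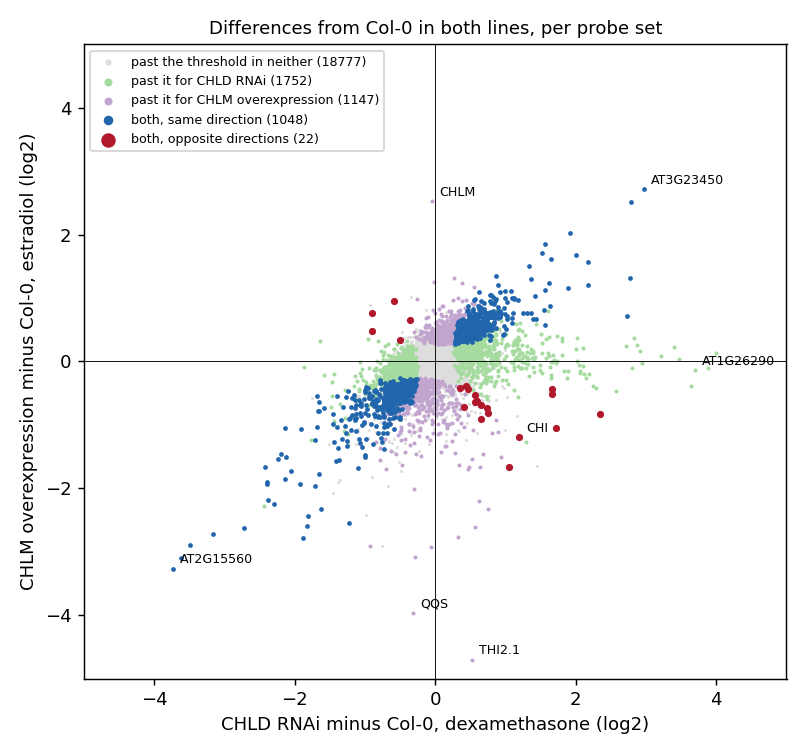
Log2 difference from Col-0 in the CHLD RNAi line (horizontal axis) and in the CHLM overexpression line (vertical axis), 1 point per probe set, coloured by which of the comparisons it passed at adjusted p under 0.05. The cloud follows the diagonal (r = 0.539), with 1048 probe sets past the threshold in the same direction in both lines and 22 in opposite directions.

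The lines also differed, as tested by the difference between their effects. The largest difference was that of THI2.1, described below, which had fallen in the CHLM overexpression line. A difference between the effects also holds any difference between the Col-0 groups. Large differences were also found in genes that rose in the CHLD RNAi line and were not past the threshold in the other, such as AT3G61490 (difference -4.03, adjusted p = 4.15e-07), AT1G26290 (-3.84, adjusted p = 2.13e-07), SWEET13 (-2.98, adjusted p = 3.23e-06) and JMT (-2.63, adjusted p = 1.26e-05). QQS went the other way about, with a fall in the CHLM overexpression line and -0.31 (SE 0.153, adjusted p = 0.22) in the CHLD RNAi line (difference -3.66, adjusted p = 3.83e-07). Of 7 genes that passed in opposite directions, the chitinase gene CHI rose 2.29-fold (SE 0.213 on the log2 scale) in the CHLD RNAi line and fell by 1.19 (SE 0.213) in the CHLM overexpression line, and AT1G65920 rose by 1.66 (SE 0.13) and fell by 0.52 (SE 0.13). The fall of AT1G65920 was not past the threshold without Col-0 estradiol replicate 1 or CHLM replicate 1 or 2 (adjusted p = 0.0758, 0.0747 and 0.0559). AT3G51660, AT1G26450 and ECS1 rose by 0.46 to 0.60 in the CHLD RNAi line and fell by 0.43 to 0.63 in the CHLM overexpression line. The AT3G51660 rise was not past the threshold without Col-0 dexamethasone replicate 1 or 3 or CHLD RNAi replicate 2 or 3 (adjusted p up to 0.0856), nor was its fall without Col-0 estradiol or CHLM replicate 2 or 3 (up to 0.083). The same held for the rise of ECS1 without Col-0 dexamethasone replicate 1 (0.0562), and for its fall without Col-0 estradiol replicate 2 or 3 or CHLM replicate 1 or 2 (up to 0.0789). Over all probe sets 256 differed, 56 with a higher and 200 with a lower CHLM effect, and 147 of them by at least 2-fold. The number was 492 without Col-0 estradiol replicate 1, 126 higher and 366 lower, and the at least 2-fold differences were then 33 higher and 222 lower, against 18 and 129.

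Groups that differed were the tubulins, higher in the difference (camera adjusted p = 0.00277; adjusted p = 0.117 with an estimated correlation), and the PUB ubiquitin ligases, lower (camera adjusted p = 0.00277; adjusted p = 0.117 with an estimated correlation). Jasmonate genes were lower (camera adjusted p = 0.00277; adjusted p = 0.403 with an estimated correlation), as were genes of salicylate immunity (camera adjusted p = 0.00346; adjusted p = 0.403 with an estimated correlation). Single members past the threshold were JMT, THI2.1 (-5.22, adjusted p = 0.0485) and PUB25 (-1.27, adjusted p = 8.46e-04), which rose 2.63-fold (SE 0.117 on the log2 scale) in the CHLD RNAi line and stood at 0.13 (SE 0.117, adjusted p = 0.544) in the CHLM overexpression line. No tubulin and no salicylate gene passed. Those with the smallest p were TUB1 among the tubulins (0.54, adjusted p = 0.235) and GRX480 among the salicylate genes (-1.43, adjusted p = 0.254), and GRX480 passed without Col-0 estradiol replicate 1 (-1.84, adjusted p = 0.0158). The THI2.1 call ended without any 1 of 9 arrays, Col-0 dexamethasone replicates 1 and 3, CHLD RNAi replicates 2 and 3, Col-0 estradiol replicates 2 and 3 and CHLM replicates 1, 2 and 3 (adjusted p between 0.0908 and 0.146), and without Col-0 estradiol replicate 1 the difference was -6.40 (adjusted p = 2.77e-04). In that fit the Col-0 groups themselves differed, dexamethasone minus estradiol, by -3.03 for THI2.1 and -4.17 for PDF1.2b. Such differences enter the difference between the effects, which was then -4.23 for PDF1.2b. The jasmonate difference is therefore not one between the lines alone. The salicylate call ended without CHLD RNAi replicate 3 (adjusted p = 0.0589). In place of 4 groups, 7 passed without CHLD RNAi replicate 1 and 7 without Col-0 estradiol replicate 2.

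The comparison of Col-0 under dexamethasone with Col-0 under estradiol asks how far the wild-type plants of the inducer sets differed with no transgene. Of 11 probe sets past the threshold, 7 were higher and 4 lower under dexamethasone, and 5 had a named gene. XTH19, a xyloglucan-modifying enzyme of the cell wall, was 2.14-fold higher (8.48 ± 0.08 against 7.38 ± 0.34, SD, n = 3; adjusted p = 0.0371). AT4G33980 (1.04, adjusted p = 0.00678) and AT5G51950 (0.75, adjusted p = 0.00622) were higher too. AT1G31690 (-1.04, adjusted p = 0.0371) and EXPB1, an expansin (-0.73, adjusted p = 0.032), were lower, and another, dimmer probe set of AT1G31690 stood at -0.09. The inducer and any other difference between the sets of plants cannot be told apart here.

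This comparison rested on single arrays. The total was 4 without Col-0 dexamethasone replicate 1, 0 without replicate 2 and 5 without replicate 3. It was 5 without either of Col-0 estradiol replicates 2 and 3, 28 without CHLD RNAi replicate 2 and 21 without CHLM replicate 3. At an unadjusted p of 0.05, 2407 probe sets passed in limma with all arrays and 1757 without Col-0 dexamethasone replicate 2. The call of AT5G51950 ended without Col-0 dexamethasone replicate 2 (adjusted p = 0.053), that of AT4G33980 without replicate 1 or 2 (adjusted p = 0.0618 and 0.0882), and those of XTH19, AT1G31690 and EXPB1 without any 1 of the Col-0 dexamethasone replicates. XTH19 was not past the threshold without Col-0 estradiol replicate 3 either, EXPB1 without replicate 2 or 3, and AT1G31690 without replicate 2 or 3 or CHLM replicate 1 (adjusted p up to 0.148, 0.167 and 0.211 in that order). Without Col-0 estradiol replicate 1 the total was 728, 278 higher and 450 lower, and all 11 were among them. The defensin genes PDF1.2b and PDF1.2 were then lower under dexamethasone by -4.17 (SE 0.324, adjusted p = 1.52e-05) and -4.12 (SE 0.361), with THI2.1 at -3.03, and COR27 was higher by 1.77 (SE 0.16, adjusted p = 7.38e-05).

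In the wild type 3 groups passed, each with no single member past the threshold and each lost with an estimated correlation (adjusted p = 0.654 with an estimated correlation in each). Genes of mitosis and replication were lower under dexamethasone (camera adjusted p = 0.00332, 18 measured, smallest p BUB3.1, -0.35). Without Col-0 estradiol replicate 1 BUB3.1 passed (-0.47, adjusted p = 0.018). Genes of the ATG8 system (camera adjusted p = 0.00578, 10 measured, ATG8D, 0.31) and of branched-chain amino acid breakdown (camera adjusted p = 0.00766, 8 measured, MCCB, 0.22) were higher. The number of groups was 7 without Col-0 estradiol replicate 1, 1 without replicate 3 and 0 without replicate 2 (10 at an unadjusted p of 0.05 in camera; with all arrays fry gave 0). Without replicate 2 the adjusted p values were 0.123, 0.0797 and 0.0797 in that order, and without replicate 3 they were 0.147 for the ATG8 system and 0.102 for the amino acid group.

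**Figure D3:**
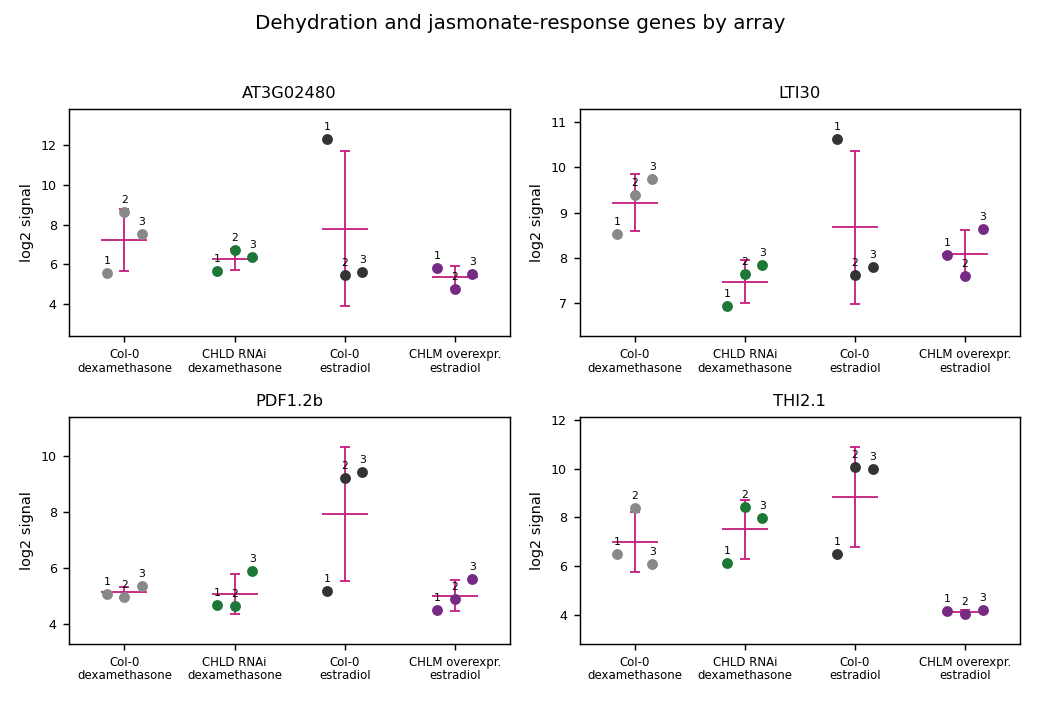
Log2 signal of AT3G02480, LTI30, PDF1.2b and THI2.1 in each of the 12 arrays, by group, with points numbered by replicate. Replicate 1 of Col-0 under estradiol lies at 12.28 for AT3G02480, against 5.49 and 5.63 in replicates 2 and 3, and at 5.19 for PDF1.2b, against 9.20 and 9.42.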

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

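The test of the difference between the effects of the lines was planned, while the choice of the 10 largest differences of each sign was made after the result was seen. For each result here, limma's test of the CHLM effect minus the CHLD effect passed an adjusted p of 0.05. In total 256 probe sets did. The positive differences were those of CHLM itself (2.57), AT3G62950 (1.97), AT5G02540 (1.31), AT2G35750 (1.27), AT1G22690 (1.23), AT1G08230 (1.15), IAA29 (1.09), AT4G33980 (1.02), AT4G01460 (0.94) and P1R1 (0.85). AT3G62950, AT5G02540 and AT4G01460 had fallen in the CHLD RNAi line, while AT2G35750 and AT1G22690 had risen in the CHLM overexpression line. IAA29 and AT1G08230 had fallen in both lines, more in the CHLD RNAi line. AT4G33980 had fallen in both to nearly the same level, 3.77 and 3.74, and its difference was close to that between the Col-0 groups (1.04, adjusted p = 0.00678). The negative differences were those of THI2.1 (-5.22), AT3G61490 (-4.03), AT1G26290 (-3.84), QQS (-3.66), AT1G80280 (-3.17), AT3G19430 (-3.12), SWEET13 (-2.98), AT4G14815 (-2.90), JMT (-2.63) and AT3G14395 (-2.62). P1R1 passed in opposite directions, with a fall by 0.51 in the CHLD RNAi line and a rise by 0.34 in the CHLM overexpression line, which was not past the threshold without Col-0 estradiol replicate 1 (adjusted p = 0.0735). Among genes that rose in the CHLD RNAi line and fell in the CHLM overexpression line, the differences were -2.39 for CHI, -2.18 for AT1G65920, -1.22 for AT3G51660, -1.10 for AT1G26450 and -0.89 for ECS1. The calls of AT3G62950 and IAA29 ended without single arrays. For AT3G62950 these were any Col-0 dexamethasone replicate, Col-0 estradiol replicate 2 or 3, or CHLM replicate 2 (adjusted p between 0.0511 and 0.0834). For IAA29 they were Col-0 dexamethasone or CHLD RNAi replicate 1 or 2, Col-0 estradiol replicate 2, or CHLM replicate 1 or 3 (adjusted p between 0.0565 and 0.0786). The THI2.1 call ended without 9 of the 12 arrays, each left out alone (adjusted p between 0.0908 and 0.146), while without Col-0 estradiol replicate 1 the difference was -6.40 (adjusted p = 2.77e-04). This value includes the difference between the Col-0 groups, which was -3.03 for THI2.1 without that array.

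As gene groups, the tubulins, the PUB ubiquitin ligases and the jasmonate genes differed between the lines at camera adjusted p = 0.00277 each, and the salicylate immunity genes at 0.00346. With an estimated correlation these were at adjusted p = 0.117, 0.117, 0.403 and 0.403.

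Other splits of the arrays within each inducer could be made in 200 ways, of which 100 were drawn. With the real one included, 6 of these 100 gave at least 256 probe sets, so that chance is not excluded by this count, and 41 gave at least the 4 gene groups found, with up to 11. The highest other count, 5315, came from the split that exchanges the line and its Col-0 group under one inducer, so that the effects common to the lines add up. This count points to a structure of the samples, their line. All 5 other splits as large kept the dexamethasone arrays parted by line. Splits that kept only the estradiol arrays parted gave at most 39 probe sets. In the 82 splits with both sets mixed the highest count was 0. Mixing puts the line effects into the spread within groups, which lowers the counts, so this 0 does not speak against chance.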

How the results depend on the processing

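The limit to the lists written first was chosen after the data were seen, and every other alternative before the data were examined. The rise of CHLM kept its call in every alternative, with log2 differences from 2.40 to 2.66. In the CHLD and CHLM comparisons the counts of at least 2-fold changes stayed within 1.5 times the reported ones in every alternative, with 252 to 302 and 109 to 194. Over 172 named gene and comparison pairs and all alternatives, 3218 values kept their direction and side of the threshold, 146 lost it, 22 gained it and 0 turned direction. These counts overstate the stability. Many alternatives cannot alter the log2 difference of a line from its Col-0 group, such as a block, other variance settings, fewer probe sets or leaving out an array not compared. Many of the genes were also named for their large changes. Where a count below differs, the cause was not tested, except that a stricter threshold lowers a count by construction.

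At an adjusted p of 0.01 the probe sets past the threshold were 1189 (CHLD), 600 (CHLM), 4 (Col-0) and 144 (difference between the effects), against 2822, 2217, 11 and 256. With only the groups compared in the fit they were 855 (CHLM) and 17 (Col-0). With array weights they were 703 (Col-0) and 447 (difference), and the correlation of the effects was 0.485 against 0.539. For Col-0 a variance trend with robust fitting gave 36, leaving out cross-hybridising probe set types 26, and median centring 32 (16 higher and 16 lower, against 7 and 4). Gene groups past the threshold, reported as 3, 7, 3 and 4 in the same order, were 0 in each with an estimated correlation (2, 5, 3 and 6 at an unadjusted p of 0.05), and 8, 10, 0 and 2 with fry (6 unadjusted in Col-0). Without dim probe sets they were 1 (CHLD) and 3 (CHLM). With only the lists written first they were 1, 1, 0 and 0 (0 unadjusted in Col-0 and 1 in the difference). In Col-0 a variance trend gave 5 and array weights 5.

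Leaving out 1 array at a time, the probe sets past the threshold ranged from 1563 to 3626 (CHLD), 1156 to 2090 (CHLM), 0 to 728 (Col-0) and 187 to 492 (difference), and the correlation from 0.439 to 0.58. The gene groups ranged from 2 to 3, 5 to 10, 0 to 7 and 4 to 7. The lowest Col-0 counts came without Col-0 dexamethasone replicate 2 (1757 probe sets at an unadjusted p of 0.05 in limma) and without Col-0 estradiol replicate 2 (10 groups unadjusted), and the highest without Col-0 estradiol replicate 1.

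With the replicate number as a block the counts were 2729, 2038, 25 and 286, and the gene groups 3, 8, 3 and 5. The numbers do not pair the samples: arrays of the same number had deviations correlated between -0.13 and 0.081, and 5 of 12 arrays lay closest to their own number. Small signals limit the test in dim probe sets, of which 6823 were left out in the alternative above.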

Other observations

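Further gene groups held members that changed. In the CHLD RNAi line EXPA9, an expansin that loosens cell walls, rose by 1.60 (SE 0.0997, adjusted p = 1.45e-07), and 4 of 18 expansins rose and 1 fell. In the CHLM overexpression line EXPA9 stood at 0.14 (adjusted p = 0.425), and the difference between the lines was -1.46 (adjusted p = 3.15e-05). There, 2 of 9 xyloglucan-modifying enzymes rose, XTH19 by 1.23 (SE 0.164) and XTH32 by 0.75 (SE 0.111). Of 20 auxin genes 2 fell in each line, IAA29 and WES1, an enzyme that conjugates auxin, which fell by 1.14 (SE 0.09) in the CHLD RNAi line and by 0.61 (SE 0.09) in the CHLM overexpression line. None of these groups passed as a whole in camera (adjusted p = 0.394 and 0.646 for the expansins, 0.944 and 0.205 for the xyloglucan enzymes, 0.173 and 0.367 for the auxin genes, in the CHLD and CHLM comparisons in turn).

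In the CHLM overexpression line 2 of 8 genes of plastid redox control rose, SAPX, a stromal ascorbate peroxidase, by 0.64 (SE 0.109), and NTRC, a thioredoxin reductase, by 0.52 (SE 0.0947; camera adjusted p = 0.649). Of 18 genes of mitosis and replication 3 rose (camera adjusted p = 0.0508), among them PSF2 (0.74, SE 0.155) and FBL17 (0.50, SE 0.115). The FBL17 call ended without Col-0 estradiol replicate 1 (adjusted p = 0.0555) or CHLM replicate 1 (adjusted p = 0.0656).

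In the paragraphs below, the tests of the time of harvest, of a wrong label, of plants short of water in one array and of the share of plastid RNA, and the reading of the spikes and of the levels of plastid genes, were chosen only after the result was seen, as were the genes AT3G02480, LEA4-5 and LEA18.

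Both lines differed from Col-0 in the same direction, with the effects correlated at 0.539 across probe sets. Water deficit in Col-0 estradiol replicate 1 alone, as the whole cause, is argued against. The correlation was still 0.48 without that array and the 260 probe sets that set it apart. Water deficit in the other Col-0 plants remains open, as the whole cause or a part, since their arrays stayed in this test. Without replicate 1, cold and dehydration genes were higher in Col-0 under dexamethasone than under estradiol (camera adjusted p = 4.89e-04, and 0.0387 for the planned cold and water deficit list). In the lines the cold and dehydration genes then had a downward sign, not past the threshold (camera adjusted p = 0.0634 for CHLD RNAi and 0.231 for CHLM overexpression). A chromosome segment that differs between Col-0 and both lines is argued against only if short, with most of the strongest common changes close together. Of 31 genes changed at least 2-fold the same way in both lines, 0 had another within 5 measured genes. Random sets gave a median of 0 and up to 2 at the 95th percentile. A long segment remains open, since changed genes spread along it need not lie within 5 measured genes of each other. A segment with few changed genes could also escape this count, and probe sets without a gene could not enter it. Another time of harvest remains open: the evening gene GI was lower in both lines by at least 7.36 SE, and COR27 stood at -3.48 and -2.56 SE in the CHLD RNAi and CHLM overexpression lines, but without Col-0 estradiol replicate 1 COR27 stood at -8.17 and -1.81 SE, the latter short of the 2 SE asked for. Also open, and untested, are a common response to altered chlorophyll synthesis, an effect of the transgenes or their inducible regulators, and a different seed stock of Col-0.

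Replicate 1 of Col-0 under estradiol stood apart from replicates 2 and 3. It was at 12.28 for AT3G02480 against 5.49 and 5.63, at 10.24 for LEA4-5 against 5.10 and 4.87, and at 6.33 for LEA18 against 2.93 and 2.89, the last 2 being genes of late embryogenesis abundant proteins, which are known from drying tissue. A Col-0 dexamethasone array under a wrong label, otherwise like the labelled ones, is argued against. Of the 260 probe sets, 65.4% lay in the range of those arrays give or take 1 on the log2 scale, so many lay outside it. The 260 were picked because this array stood apart in them. A wrongly labelled array that also differed in another way could therefore fall outside the range too, and remains open. The correlation of this array was 0.993 on average with the Col-0 dexamethasone arrays and 0.99 with replicates 2 and 3. A brighter hybridisation remains open: the mean level of a probe set took up 0.0551% of the variance of the deviation, but the deposited arrays were on a common scale, which would hide such a trend, and the hybridisation spikes were at 10.8 in this array against 9.88 to 10.3 in the others, with its poly-A spikes the highest too (6.44). Plants short of water remain a candidate explanation: the median of 14 cold and dehydration genes lay 0.928 higher on the log2 scale in this array, above the 0.11 of the 95th percentile of matched random lists, and whether this array's plants were handled otherwise is untested.

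Plastid-encoded transcripts rose and fell side by side in both lines, among the rises petA by 0.91 (SE 0.156) and 0.76 (SE 0.156) and rbcL by 0.51 (SE 0.108) and 0.50 (SE 0.108) in the CHLD RNAi and CHLM overexpression lines. A changed share of plastid RNA as the only cause is argued against, since 18.8% of the plastid genes past the threshold in the CHLM overexpression line and 33.3% in the CHLD RNAi line moved against the majority. A squeezed or stretched signal range remains open, alone or with a changed share. The largest ratio of the median change of nuclear genes of the same mean level to that of the plastid genes was -0.023, but the common scale of the arrays holds the former near 0, and the falls lay at higher signal levels than the rises: all 3 falls in the CHLM overexpression line, from 10.02 upward, lay above every rise, the highest at 9.70, as did 4 of 5 in the CHLD RNAi line. A biological cause, such as an effect of the transgenes, is open and untested.

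For 3 arrays against 3 there are only 10 splits, so the share as large as the real one is never under 0.1. The real split of the CHLD comparison gave 2822 probe sets, 284 of them at least 2-fold, and the highest other split 0 and 0 (at most 944 at an unadjusted p of 0.05 in limma, against 5966). The real split of the CHLM comparison gave 2217 and 153, and the highest other 0 and 0 (at most 1774 unadjusted, against 5730). In these other splits the effect of the line enters the spread within groups and lowers the counts, so a 0 there shows little. For the wild type the real split gave 11 and the highest other 6. At an unadjusted p of 0.05 in limma another wild-type split gave more, 2696 against 2407. The gene groups were 3 against a highest other of 5 in the CHLD comparison (2 of 10 splits as large), 7 against 7 in the CHLM comparison (3 of 10) and 3 against 9 in the wild type (6 of 10). For the correlation of the effects 2 of 100 splits, the real one included, were as large as 0.539, a share under the 0.05 asked for. The highest other was 0.574, above the real one, and the 100 splits only cross the 10 of each inducer. Chance is therefore not called excluded.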
